A study of Mus musculus with 6 samples.

How the data were processed

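Total RNA from epididymal white fat of 6 male mice aged 10 weeks was measured on Affymetrix MOE430v2.0 arrays, 1 mouse per array. The labels put 3 mice in the transgenic group and 3 in the wild type group. The mice are separate animals, so p-values measure the spread between mice together with that of sample handling. The series description calls the controls litter-matched, but no label says that a replicate number marks a litter.

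The deposited values are linear signal intensities, 1 per probe set and array, computed by the authors with MAS5, per the submitters' processing notes. MAS5 summarises the probes of a probe set into 1 signal and usually scales each array to a target mean. The version, the target and any detection calls are not given in the sources used here. The trimmed mean signal of the arrays ran from 198.5 to 255.6 in the deposited intensity table, so the arrays do not share 1 exact mean on the scale as deposited. There are 0 columns of other samples. Signals below about the 16 used as offset are close to background, and without detection calls no bound could be set on a fold change against such a signal. The number of arrays limits the precision.

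Probe sets were paired with genes through the platform annotation table given for this series. Of 45101 probe sets, 34958 have 1 gene, 932 have several and 9211 have none in that table. Genes were named only from probe sets with 1 gene, which gave 18194 symbols. Matching the gene identifiers to current symbols changed 0 names, and the identifiers of 204 probe sets were not in the reference table. No genome build is used and no coordinates are given.

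Analysis was done in R 4.3.3 with limma 3.58.1, and in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. The log2 of signal + 16 was tested without further normalization. The 64 control probe sets were left out, and then the 40% of probe sets with the lowest mean log2 value over all 6 arrays, which left 27023. Group means were compared with lmFit and eBayes (trend = TRUE), two-sided, with 4 residual degrees of freedom before moderation, and p-values were adjusted by the Benjamini-Hochberg method over all tested probe sets, with a threshold of 0.05. Every adjusted p of a gene is from this limma test. Fold changes are on the log2(signal + 16) scale, which understates the change of dim genes. A gene was represented by its tested probe set with the highest mean over all 6 arrays, which gave 13112 genes.

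The design and the rule for named genes were fixed before the data were examined. The rule takes the 10 genes with the largest rise and the 10 with the largest fall among genes past the threshold whose groups do not overlap. For each list with an adjusted camera p under 0.05 or with at least 3 members past the threshold, it adds up to 4 of the members past the threshold with the largest absolute change. It also takes 13 genes chosen from the design, of which 11 were measured: Srebf1, Fabp4, Pparg, Cebpa, Adipoq, Lep, Fasn, Scd1, Cdkn1a, Adgre1 and Slc2a4. This gave 88 genes. In the same way 41 gene lists (pathways, cell types and neighbouring tissues) were fixed and tested with limma's camera, with a preset inter-gene correlation of 0.01, on the representative probe sets. Their p-values were adjusted over the 41 lists.

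On simulated data with the spread of the real arrays and 200 of 27023 probe sets changed, the 6-array comparison recovered 34.6% of changes of log2 2 and 0% of changes of log2 1. The comparison without transgenic replicate 2 recovered 84.4% and 11.2%. False calls were 0.575% and 5.35% of all calls. Camera was checked in independent noise, without correlation between genes and with the same spread on every array. It called 20 of 20 simulated lists of 30 genes shifted by log2 1, and 0 unshifted lists. Correlated genes were not simulated, so this check says nothing about false calls in lists of correlated genes.

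Alternatives were other offsets (1 and 64), no filter and a filter of 60%, quantile normalization, centring on array medians, eBayes without trend or robust, array weights, the replicate number as a block, each of the 6 arrays left out in turn, the mean over all probe sets of a gene, and an estimated inter-gene correlation. After the quality of transgenic replicate 2 was seen, its removal was also combined with quantile normalization, with a block for the class of Pcx ratio (under 10 or above) and with an estimated correlation.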

Results

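Gene expression was measured in epididymal white fat of male mice aged 10 weeks. One group carried a transgene that expresses the nuclear form of SREBP-1c, a transcription factor of lipid synthesis, from the aP2 (Fabp4) promoter of fat cells. The labels describe these mice as lipodystrophic, a state in which fat tissue is lost or poorly formed. The other group were wild type littermates. RNA of each mouse was hybridised to its own Affymetrix mouse expression array, with 3 mice per group, and this number limits the precision of every value. The deposited table held a MAS5 signal (a linear intensity) for 45101 probe sets. The median signal was 53.4 to 65.4 on 5 arrays and 37.7 on the array of transgenic replicate 2.

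That array stood apart in the quality of its RNA. On it the 3′ probe set of the beta-actin control was 122 times as bright as the 5′ probe set, against 1.12 to 1.81 times on the other 5 arrays, and for Gapdh the ratio was 55.9 against 0.772 to 1.22. A high ratio is the usual sign of shortened RNA on these arrays. The first principal component of the tested probe sets (64.6% of the variance) separated this array from the rest, and the second (21.5%) separated transgenic replicates 1 and 3 from the wild type arrays. A different split appeared in the Pcx control, whose 3′ over 5′ ratio was 3.06 in wild type replicate 3 and 3.10 in transgenic replicate 1, and 40.6, 52.0, 14.1 and 44.2 in wild type replicates 1 and 2 and transgenic replicates 2 and 3. Values without transgenic replicate 2 are therefore given with the counts of each gene group.

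**Figure D1:**
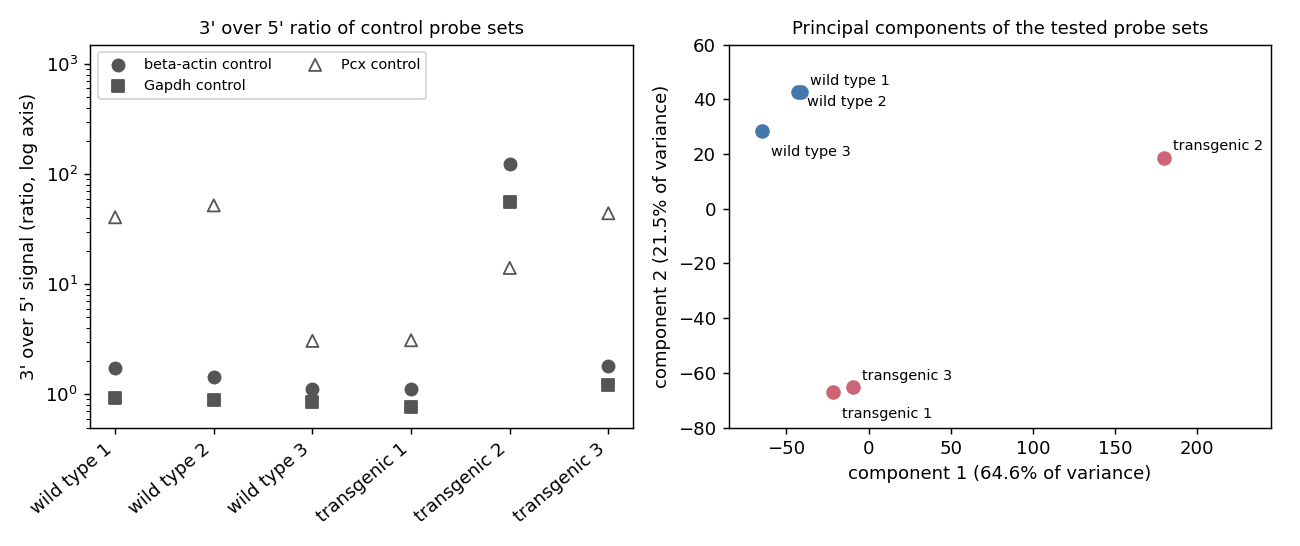
Left, ratio of 3′ to 5′ signal (log axis) of the beta-actin, Gapdh and Pcx control probe sets on each of the 6 arrays; right, the first and second principal components of the tested probe sets, 1 point per array (blue wild type, red transgenic). Transgenic replicate 2 has a beta-actin ratio of 122 and a Gapdh ratio of 55.9 and lies apart from the other 5 arrays on component 1.

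The comparison of transgenic with wild type fat asked which RNAs differ in the fat of mice with this form of lipodystrophy. In the transgenic fat 14 of 21 genes of cholesterol synthesis and uptake and 13 of 26 genes of fatty acid synthesis rose, as did 11 of 48 macrophage markers and 5 of 32 lysosome genes, while 7 of 40 adipocyte markers fell. All 5 of these lists passed the camera test with its preset correlation but not with an estimated one (adjusted p = 0.345 and 0.272 with an estimated correlation for the synthesis lists and 0.403 for each of the others). Fabp3, the fatty acid binding protein of heart muscle, rose 82.1-fold (log2 fold change 6.36 ± 0.29 SE, adjusted p = 0.000803), and Ptgds, a prostaglandin D synthase, rose 73.6-fold (6.20 ± 0.21 SE, adjusted p = 0.000248). Bdh1, a mitochondrial enzyme of ketone body metabolism, had a log2 fold change of 6.62 ± 0.42 SE (adjusted p = 0.00142), from a wild type mean signal of 8.9 that is close to background. With an offset of 64 in place of 16 before the logarithm this became 5.03, against 5.58 for Fabp3 and 5.69 for Ptgds. The largest falls were those of the imprinted gene Nnat (−7.23 ± 0.24 SE, adjusted p = 0.000248), Tmem45b (−6.78 ± 0.32 SE, adjusted p = 0.000811) and Pck1, the cytosolic enzyme that feeds glyceride-glycerol synthesis in fat (−5.60 ± 0.30 SE, adjusted p = 0.000924). The mean signal of Nnat was 9262 ± 846 (SD, n = 3) in wild type and 46.0 ± 9.9 (SD, n = 3) in transgenic fat.

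The other genes of the top 10 rises were Fabp7, the brain-type fatty acid binding protein, Pdzk1ip1, the transglutaminase gene Tgm5, the lipid esterase gene Aadac, Plekhd1, Tnnt2, which encodes cardiac troponin T, and Mvd of the mevalonate pathway. Their log2 fold changes ran from 5.66 for Fabp7 to 4.51 for Mvd. The other genes of the top 10 falls were Sncg (γ-synuclein), the lactate receptor gene Hcar1, the amino acid transporter gene Slc7a10, the secreted Wnt antagonist gene Sfrp5, the serine synthesis gene Phgdh, the potassium channel gene Kcnj15 and the GABA transporter gene Slc6a13. These ran from −5.07 for Sncg to −4.01 for Slc6a13, whose adjusted p was up to 0.0679 with 1 array left out. Like Bdh1, Tnnt2 and Plekhd1 had mean wild type signals (3.2 and 12.7) below the 16 added before the logarithm, so that the sizes of these changes and their ranks depend on that offset. The same holds in part for Fabp7, Tgm5 and Aadac, with wild type means of 19.8, 18.0 and 23.0, and for Hcar1 and Kcnj15, with transgenic means of 23.1 and 19.5, and for Tmem45b and Slc6a13, which were also dim in transgenic fat. No named gene had another probe set that passed the threshold in the opposite direction. Among the top 10 rises and falls, the other tested probe set of Bdh1, of Fabp3 and of Mvd did not pass it. Those of Ptgds, Pdzk1ip1, Tnnt2, Pck1, Sfrp5 and Phgdh passed it in the same direction. Many further called genes with other tested probe sets also had none of these past it. Among them were Hsd17b7, Rsad2, Fads1, Plod2, Gpam, Rgs5 and Cdkn1a. The second probe set of Cdkn1a had 0.29 ± 1.59 SE (adjusted p = 0.939), and 2.11 (adjusted p = 0.109) without transgenic replicate 2.

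Of 27023 probe sets tested with limma, 802 passed an adjusted p of 0.05, 452 higher and 350 lower in transgenic fat, and in all 802 the groups did not overlap. They were among 7362 probe sets without overlap, 27.2% of those tested, where chance gives 10%. By gene, 292 of 13112 rose and 202 fell. The lack of overlap means that each of these 802 directions also holds within both classes of Pcx ratio. Without transgenic replicate 2 the count was 3565 (1882 higher, 1683 lower), and this included all of the 802 with the same sign. The count was 180, 141 and 187 without wild type replicate 1, 2 and 3, and 326 without transgenic replicate 3. Of 81 named genes past the threshold, 39 passed it whichever array was left out, and all 81 passed it without transgenic replicate 2. The calls of 38, 42 and 36 were lost without wild type replicate 1, 2 and 3, and of 13 and 29 without transgenic replicates 1 and 3; the highest adjusted p with 1 array left out stands beside such genes. The median log2 fold change of all tested probe sets was −0.09, and 0.02 after quantile normalization, and changes are to be read against this median.

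Genes of cholesterol synthesis and uptake had the lowest camera p of the 41 lists. Of 21 measured members 14 rose, none fell (0) and 7 did not pass the test; adjusted over the list alone 15 were higher. Mvd rose 22.8-fold (4.51 ± 0.40 SE, adjusted p = 0.00348), the lanosterol demethylase gene Cyp51 16.2-fold (4.02 ± 0.22 SE, adjusted p = 0.000982) and the lanosterol synthase gene Lss 13.6-fold (3.76 ± 0.24 SE, adjusted p = 0.00142). Hsd17b7, a reductase of the same pathway, rose by 3.63 ± 0.46 (adjusted p = 0.011, up to 0.0844 with 1 array left out). The list ranked high among all genes by camera (adjusted p = 1.93e-15; adjusted p = 0.345 with an estimated correlation). Leaving out transgenic replicate 2 gave 17 that rose and 0 that fell.

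Among 26 genes of fatty acid synthesis 13 rose, 0 fell and 13 did not pass the test, with 17 higher when adjusted over the list alone. The acyl-CoA synthetase gene Acsl3 rose 20.5-fold (4.36 ± 0.31 SE, adjusted p = 0.00201), Mid1ip1, a regulator of acetyl-CoA carboxylase, 7.14-fold (2.84 ± 0.19 SE, adjusted p = 0.00158) and the fatty acid desaturase gene Fads1 5.40-fold (2.43 ± 0.21 SE, adjusted p = 0.00327). The elongase gene Elovl3 rose by 2.52 ± 0.49 (adjusted p = 0.0467, up to 0.214 with 1 array left out). The list's camera adjusted p was 3.06e-11 (adjusted p = 0.272 with an estimated correlation), and 17 members rose without transgenic replicate 2. Srebf1, the gene that encodes SREBP-1, rose by 1.08 ± 0.19 (adjusted p = 0.0342, up to 0.188 with 1 array left out). Whether its probe set reads the transgene is not given in the sources used here, so this value checks nothing about the transgene.

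Some lipid genes with very bright probe sets did not pass the test. Fasn, the fatty acid synthase gene, had a log2 fold change of −0.18 ± 0.29 SE (adjusted p = 0.782), and 0.18 (adjusted p = 0.405) without transgenic replicate 2. Scd1, a stearoyl-CoA desaturase gene, had 0.01 ± 0.10 SE (adjusted p = 0.974), and Fabp4, whose promoter drives the transgene, 0.00 ± 0.10 SE (adjusted p = 0.996). The wild type mean signals of Fabp4, Scd1 and Fasn ranked 3, 12 and 34 among all probe sets and lay 0.18, 0.37 and 0.62 log2 units below the highest signal on any array (15133). Of the 22 genes at least as bright as Fasn in wild type fat, 0 rose and 2 fell, and without transgenic replicate 2, 0 rose and 5 fell. This choice by wild type signal leaves out genes that were so bright only in transgenic fat, so the counts lean towards falls. Plin2, Aldh1a7 and Hsd17b12 rose to transgenic mean signals of 10991, 9971 and 9890, above the wild type mean of Fasn (9847). Dimmer probe sets of these genes, looked at after the data were seen, differed among themselves. For Fabp4 they had −0.03 ± 0.12 SE (adjusted p = 0.925), −0.73 ± 0.26 SE (adjusted p = 0.235) and −2.47 ± 0.91 SE (adjusted p = 0.247), and −0.02, −0.91 and −1.47 (adjusted p = 0.934, 0.0196 and 0.0686) without transgenic replicate 2. A second probe set of Scd1 had 0.78 ± 0.80 SE (adjusted p = 0.651), and 1.12 (adjusted p = 0.38) without that array.

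**Figure D2:**
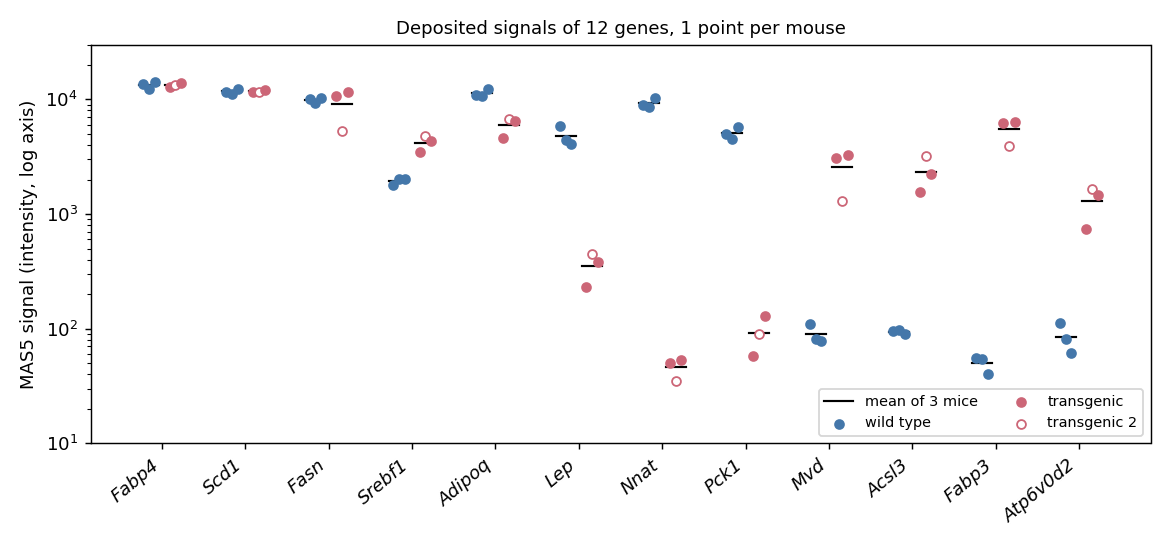
Deposited MAS5 signal (linear intensity, log axis) of 12 genes, 1 point per mouse, with wild type in blue, transgenic in red (open for transgenic replicate 2) and the mean of 3 mice as a bar. Fabp4, Scd1 and Fasn lie near the top of the scale in both groups, while Nnat falls from a mean of 9262 to 46.0 and Fabp3 rises from 50 to 5509.

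More markers of mature fat cells fell than rose. Of 40 measured adipocyte markers 7 fell, 2 rose and 31 did not pass the test, with 20 lower and 7 higher when adjusted over the list alone. Besides Nnat, Pck1 and Sncg, the leptin gene Lep fell by 3.74 on the log2 scale (SE 0.31, adjusted p = 0.00302), from a mean signal of 4802 ± 946 to 353 ± 112 (SD, n = 3). Adipoq, which encodes adiponectin, fell by 0.93 (SE 0.18, adjusted p = 0.0448, up to 0.217 with 1 array left out). The members that rose were Gpam, an enzyme of glycerolipid synthesis (1.33 ± 0.20 SE, adjusted p = 0.0223, up to 0.101 with 1 array left out), and Apoc1 (2.10, adjusted p = 0.00327), an apolipoprotein gene named after its values were seen. The camera adjusted p was 0.000119, downward (adjusted p = 0.403 with an estimated correlation). Leaving out transgenic replicate 2 gave 20 markers that fell and 8 that rose. All 5 members of the adipokine list that passed the test fell: Sfrp5, Lep, the haptoglobin gene Hp (−2.51), Nrg4 (−1.98) and Adipoq, while 19 did not pass it. The adjusted p of Hp and Nrg4 were up to 0.0786 and 0.0892 with 1 array left out. Adjusted over the list alone 5 were higher and 9 lower, and without transgenic replicate 2, 5 rose and 8 fell. The list itself was not called (camera adjusted p = 0.0756).

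Among 26 adipogenic transcription factors Srebf1 rose, Ebf2 (−1.72 ± 0.31 SE, adjusted p = 0.0386, up to 0.202 with 1 array left out) and Klf15 (−1.66 ± 0.26 SE, adjusted p = 0.0242, up to 0.161) fell, and 23 did not pass the test; adjusted over the list alone, 4 were higher and 7 lower. The list's camera adjusted p was 0.0321, downward (adjusted p = 0.403 with an estimated correlation), and 0.0721 without transgenic replicate 3. Without transgenic replicate 2, 5 rose and 11 fell. The master regulator genes Pparg and Cebpa had log2 fold changes of −0.85 ± 0.30 SE (adjusted p = 0.227) and −2.46 ± 0.72 SE (adjusted p = 0.153). Without transgenic replicate 2 these were −1.13 (adjusted p = 0.00237) and −1.53 (adjusted p = 0.000153).

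Of 16 measured lipolysis genes, Hcar1, the nicotinic acid receptor gene Hcar2 (−3.13 ± 0.27 SE, adjusted p = 0.00327, to a mean signal of 18.1 that is close to background) and the natriuretic peptide clearance receptor gene Npr3 (−3.21 ± 0.47 SE, adjusted p = 0.0182, up to 0.111 with 1 array left out) fell, none (0) rose and 13 did not pass the test. Hcar1 and Hcar2 encode receptors that restrain lipolysis. Adjusted over the list alone 9 were lower and 1 higher, and without transgenic replicate 2, 9 fell and 1 rose. By camera the adjusted p was 8.13e-05, downward (adjusted p = 0.272 with an estimated correlation). Of 28 genes of insulin signalling and glucose uptake 3 fell, and 25 did not pass the test; adjusted over the list alone 3 were lower. They were Grb14, an adaptor that inhibits the insulin receptor (−2.71 ± 0.25 SE, adjusted p = 0.00394), and the binding protein genes Igfbp5 (−1.80, adjusted p up to 0.0892 with 1 array left out) and Igfbp3 (−1.57, up to 0.187). Camera gave an adjusted p of 8.15e-05, downward (adjusted p = 0.403 with an estimated correlation). Slc2a4, the insulin-responsive glucose transporter gene, had −1.25 ± 0.45 SE (adjusted p = 0.236), and −0.72 (adjusted p = 0.015) without transgenic replicate 2, when 9 members fell and 1 rose.

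**Figure D3:**
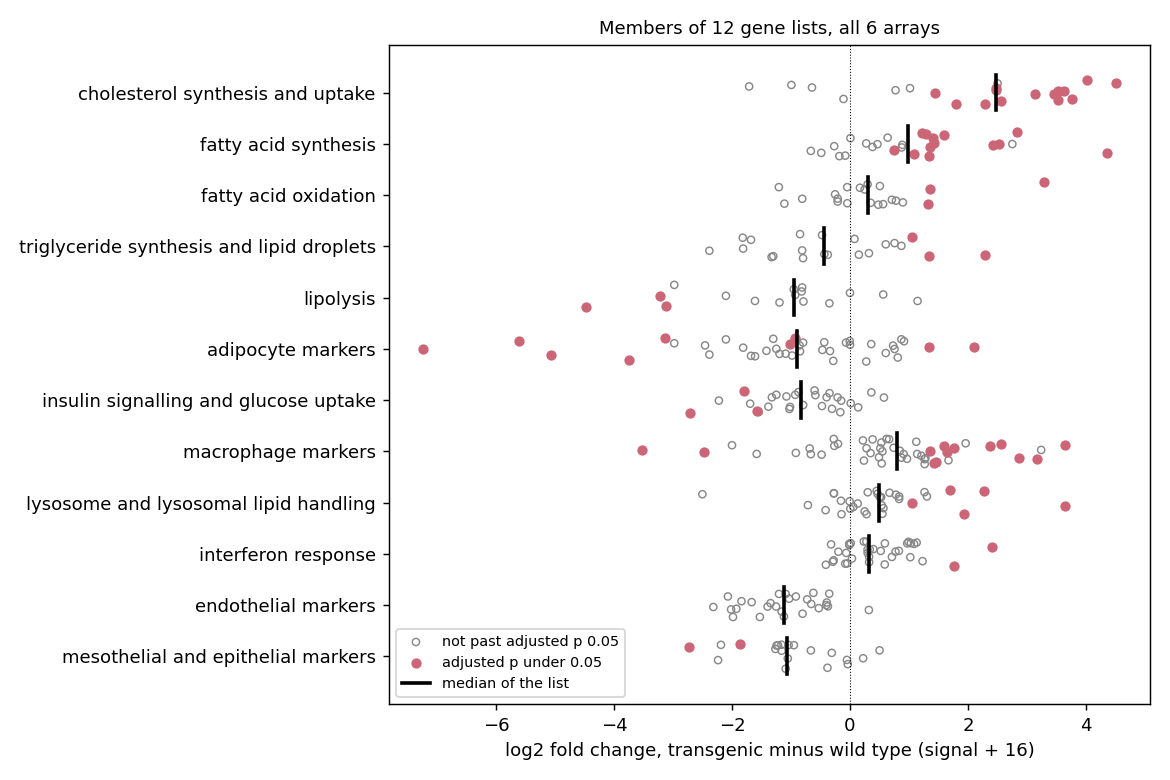
Log2 fold change (transgenic minus wild type, x axis) of each measured member of 12 gene lists, 1 circle per gene over all 6 arrays, filled where the adjusted p is under 0.05; black bars mark list medians. The medians of cholesterol and fatty acid synthesis lie at 2.48 and 0.98, and those of adipocyte and endothelial markers at −0.89 and −1.12.

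More macrophage markers rose than fell. Of 48 measured markers 11 rose, 2 fell and 35 did not pass the test, with 21 higher and 4 lower when adjusted over the list alone. Atp6v0d2, a subunit of the lysosomal proton pump, rose 12.6-fold (3.65 ± 0.38 SE, adjusted p = 0.00559), the C-type lectin gene Clec4d 9.04-fold (3.18 ± 0.37 SE, adjusted p = 0.00833) and the metalloelastase gene Mmp12 7.27-fold (2.86 ± 0.55 SE, adjusted p = 0.0473). The highest adjusted p of these 3 genes with 1 array left out were 0.0527, 0.0645 and 0.148. The members that fell were Retnla (−3.52 ± 0.34 SE, adjusted p = 0.00425), a marker of alternatively activated macrophages, and Mgl2 (−2.47, adjusted p = 0.0204), a lectin gene named after its values were seen. Adgre1, which encodes F4/80, had 1.67 ± 0.33 SE (adjusted p = 0.0516), and 1.43 (adjusted p = 0.00506) without transgenic replicate 2. The camera adjusted p was 3.76e-08 (adjusted p = 0.403 with an estimated correlation), and without transgenic replicate 2, 28 markers rose and 4 fell. Of 32 lysosome genes 5 rose, 0 fell and 27 did not pass the test, with 13 higher when adjusted over the list alone. They included Gla (2.27 ± 0.21 SE, adjusted p = 0.00387), which encodes α-galactosidase, and the acid lipase gene Lipa (1.94 ± 0.27 SE, adjusted p = 0.0153), with adjusted p up to 0.0551 and 0.0999 when 1 array was left out. The list's camera adjusted p was 3.40e-06 (adjusted p = 0.403 with an estimated correlation), and 16 members rose without transgenic replicate 2.

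Among the other immune lists 4 also ranked higher by camera, on fewer genes. Of 34 cytokine and chemokine genes 2 rose and 32 did not pass the test, with 6 higher when adjusted over the list alone. The chemokine genes Ccl8 (6.38-fold) and Cxcl2 (3.99-fold) had adjusted p of 0.00618 and 0.00643, up to 0.0619 and 0.0632 with 1 array left out. By camera the adjusted p was 8.97e-05 (adjusted p = 0.403 with an estimated correlation). Of 35 interferon response genes 2 rose, Rsad2 (2.41 ± 0.24 SE, adjusted p = 0.00527) and Ifit3 (1.77 ± 0.24 SE, adjusted p = 0.0143, up to 0.126 with 1 array left out), and 33 did not; adjusted over the list alone 5 were higher. Camera gave an adjusted p of 0.000146 (adjusted p = 0.403 with an estimated correlation). Among 17 neutrophil and mast cell markers the antimicrobial peptide gene Camp (2.96, from a wild type mean signal of 5.2 that is below the offset of 16, on which the value depends) and the mast cell protease genes Cpa3 (1.65, adjusted p up to 0.133 with 1 array left out) and Cma1 (1.60, up to 0.209) rose, and 14 did not pass the test (5 higher and 1 lower adjusted over the list alone). The camera adjusted p was 0.00111 (adjusted p = 0.403 with an estimated correlation). Of 15 B cell and plasma cell markers Jchain alone rose (2.57 ± 0.49 SE, adjusted p = 0.0448, up to 0.203 with 1 array left out), with 4 higher adjusted over the list alone. Its camera adjusted p was 0.00403 (adjusted p = 0.403 with an estimated correlation), and 0.146 without transgenic replicate 1. Without transgenic replicate 2, 9 cytokine genes, 14 interferon genes, 8 neutrophil and mast cell markers and 4 B cell and plasma cell markers rose, and 1 neutrophil and mast cell marker fell. T and NK cell markers were not called (camera adjusted p = 0.192), and 1 of them rose without transgenic replicate 2. Dendritic cell and MHC class II genes were not called either. Their median was 0.04 without transgenic replicate 2 and −0.27 with all 6 arrays (camera adjusted p = 0.996 and 0.456, downward). Of 16 measured 0 passed the limma test, with 3 at an unadjusted p under 0.05, all lower, and 2 rose without transgenic replicate 2.

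Markers of vessels and of the mesothelium, the cell layer that covers the fat pad, ranked lower by camera. Of 27 endothelial markers none (0) passed the limma test, either over all genes or adjusted over the list alone (10 at an unadjusted p under 0.05, all lower), but their median was −1.12 and the camera adjusted p 3.32e-06, downward (adjusted p = 0.403 with an estimated correlation). The median was −0.62 without transgenic replicate 2, when 14 fell and 0 rose; in that degraded array alone it was −2.27. Among 20 smooth muscle and pericyte markers Mcam (−2.65 ± 0.23 SE, adjusted p = 0.00327), Synpo2 (−2.53 ± 0.29 SE, adjusted p = 0.00755, up to 0.0667 with 1 array left out) and Rgs5 (−1.27 ± 0.23 SE, adjusted p = 0.0393, up to 0.21) fell and 17 did not pass the test; adjusted over the list alone 3 were lower and 1 higher. By camera the adjusted p was 0.0073 (adjusted p = 0.437 with an estimated correlation), and 6 fell and 2 rose without transgenic replicate 2. Of 20 mesothelial and epithelial markers Msln, the mesothelin gene (−2.72 ± 0.50 SE, adjusted p = 0.0392), and the keratin gene Krt19 (−1.86 ± 0.33 SE, adjusted p = 0.0348) fell, each with an adjusted p of up to 0.202 when 1 array was left out. The other 18 did not pass the test, and 10 were lower adjusted over the list alone. The list's camera adjusted p was 1.36e-05 (adjusted p = 0.403 with an estimated correlation), and 11 fell without transgenic replicate 2.

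Some genes of further groups passed the test. Of 21 fatty acid oxidation genes 3 rose and 18 did not pass the test: the peroxisomal gene Ehhadh (3.29 ± 0.36 SE, adjusted p = 0.00618), Cpt1a (1.36 ± 0.22 SE, adjusted p = 0.0263, up to 0.173 with 1 array left out) and Slc25a20 (1.33 ± 0.26 SE, adjusted p = 0.0493, up to 0.223). Adjusted over the list alone 5 were higher, and without transgenic replicate 2, 7 rose. The camera adjusted p was 0.00403 (adjusted p = 0.403 with an estimated correlation). Of 18 brown and beige adipocyte genes 4 rose, including Fabp3 and the muscle-type cytochrome oxidase gene Cox8b (3.09 ± 0.31 SE, adjusted p = 0.00492), 2 fell and 12 did not pass the test, and the list was not called (camera adjusted p = 0.0756). On the list of glucocorticoid and steroid metabolism 4 of 16 genes rose, led by Cyp2f2 (3.61 ± 0.24 SE, adjusted p = 0.00155) and Star (2.69 ± 0.26 SE, adjusted p = 0.00416). The others were Aldh1a7 and Hsd17b12, and that list was not called either (camera adjusted p = 0.0707). Cyp2f2 also stands on a list of liver genes below, so the count describes this list rather than steroid metabolism as such. Of 21 genes of triglyceride synthesis and lipid droplets 3 rose, Gpam and the droplet coat genes Plin5 (2.29, adjusted p up to 0.174 with 1 array left out) and Plin2 (1.06, up to 0.101), and 18 did not pass the test. Of 29 cell cycle inhibitors and p53 targets 4 rose: Eda2r (1.86), Trp53inp1 (1.85) and Cdkn2b (1.49), with adjusted p up to 0.107, 0.188 and 0.26 when 1 array was left out, and Cdkn1a (1.33 ± 0.22 SE, adjusted p = 0.0283, up to 0.185 with 1 array left out); the lists of these last 2 groups were not called (camera adjusted p = 0.673 and 0.229). Adjusted over the list alone, 5 brown and beige genes were higher and 3 lower. On the same basis 5 members of the steroid list were higher and 1 lower. For triglyceride and droplet genes 5 were higher and 5 lower, and for cell cycle inhibitors and p53 targets 5 higher and 2 lower. With transgenic replicate 2 left out, 6 brown and beige genes rose and 3 fell (camera adjusted p = 0.00273, and 0.57 with an estimated correlation). In the same setting 5 members of the steroid list rose and 3 fell. Among triglyceride and droplet genes 6 then rose and 7 fell, and among cell cycle inhibitors and p53 targets 9 rose and 5 fell.

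A few more lists passed camera on small shifts. The oxidative stress list ranked higher (camera adjusted p = 0.00387; adjusted p = 0.458 with an estimated correlation), and the metallothionein gene Mt1 alone of 31 members rose (1.49 ± 0.15 SE, adjusted p = 0.00565, up to 0.0522 with 1 array left out); adjusted over the list alone 8 were higher and 1 lower, and without transgenic replicate 2, 13 rose and 4 fell. The collagen and matrix list ranked lower (camera adjusted p = 0.00222; adjusted p = 0.643 with an estimated correlation), although the only one of 47 members to pass the test was Plod2, a collagen lysyl hydroxylase gene, which rose by 2.56 ± 0.23 (adjusted p = 0.0036). Adjusted over the list alone 3 matrix genes were lower and 1 higher, and without transgenic replicate 2, 11 fell and 2 rose. Oxidative phosphorylation genes (55 measured, 0 past the limma test and 10 at an unadjusted p under 0.05) had a median of 0.22 and a camera adjusted p of 0.00315, with an adjusted p = 0.638 with an estimated correlation. This call ended without transgenic replicate 2 (adjusted p = 0.0655, 1 gene higher) and with quantile normalization (adjusted p = 0.32). Cell cycle genes (45 measured, 0 past the limma test and 3 at an unadjusted p under 0.05) had a median of 0.21 and a camera adjusted p of 0.035 (adjusted p = 0.682 with an estimated correlation). This call ended without wild type replicate 2 or 3 or transgenic replicate 1 or 2 (adjusted p = 0.181, 0.153, 0.0548 and 0.16), and 0 members passed the limma test without transgenic replicate 2.

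In all, 20 of 41 lists passed camera, and 0 did so with an estimated correlation. That setting also uses the 4 residual degrees of freedom, so few lists could pass it. For lipolysis the estimated correlation was −0.0107, below the preset 0.01, and the adjusted p still went from 8.13e-05 to 0.272. The loss of the calls therefore cannot be put down to correlation between genes alone. The lists for epididymis (10 of 37 genes measured) and male germ cells (6 of 30 measured), tissues that lie beside this fat pad, had 0 members past the limma test. At an unadjusted p under 0.05 of that test 2 epididymis genes were lower and 2 germ cell genes higher. Without transgenic replicate 2, 2 epididymis and 0 germ cell genes fell, and 0 of either list rose. Hypoxia genes included 3 that fell, Pfkfb3 (−2.41), Bnip3 (−1.46) and Fgf1 (−1.42), whose adjusted p were up to 0.146, 0.146 and 0.214 with 1 array left out, with 20 not past the test, and that list was not called (camera adjusted p = 0.264). Adjusted over the list alone 3 hypoxia genes were higher and 9 lower, and without transgenic replicate 2, 3 rose and 7 fell. In the complement, immediate early gene, matrix protease and neuron and Schwann cell lists the median lay below 0 while camera pointed upward, and none of these was called. Without transgenic replicate 2 these medians were 0.27, 0.27, 0.17 and 0.08, on the same side as camera. The ribosomal protein list had a median of 0.16 and a mean of −0.02 and was not called. Ucp1 was not analysed here.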

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

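The tests in this part were chosen after the results were seen, except the count over other splits of the samples, which was planned.

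The control probe sets for beta-actin and Gapdh take no part in the comparison of groups, and in transgenic replicate 2 their 3′ over 5′ ratios of 122 and 55.9 lay above the wild type range of 1.12 to 1.73 and 0.844 to 0.931.

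Transgenic replicate 2 stood apart from the other 5 arrays. The tables argue against a wild type sample under a transgenic label: of the 3565 probe sets called without this array, 81.2% had it on the side of the other transgenic arrays. They also argue against scaling, since after quantile normalization its highest correlation across probe sets with another array was 0.803, below the lowest of 0.889 among the other 5. Degraded RNA remains, and its smaller control ratio was 46.0 times the highest ratio on the other arrays, so that degradation is a candidate explanation for the distance of this array. No biological explanation was tested.

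The macrophage list ranked higher and the endothelial list lower by camera, both with an adjusted p = 0.403 with an estimated correlation, and 0 of 27 endothelial markers passed the limma test (10 at an unadjusted p under 0.05). A smaller share of fat cells alone would raise the markers of all other cell types alike. But the median change of the macrophage list exceeded that of the endothelial list by at least 1.47 log2 units in each of the 3 transgenic arrays, against an SD of 0.12 among the wild type arrays. The pattern itself prompted this difference, which speaks only against a smaller share of fat cells as the only cause. A contribution of such a share to the macrophage rise stays open. The smaller difference among transgenic replicates 1 and 3 was also 1.47, which argues against the degraded array as the source, although that array had the largest difference, 3.13. Of the macrophage list 12 members, and of the endothelial list 1, are also on another list, and the tested members of both lists had measurable signal in this tissue. Whether more macrophages are present or each expresses more of these genes stays open.

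Of the 10 ways to split the 6 arrays into 3 and 3, only the real one (1 of 10) gave as many as its 802 called probe sets, and the highest of the others gave 0 by limma. At an unadjusted p under 0.05 the real split had 4438 probe sets and the others at most 1495. With 10 splits the share cannot fall under 0.05.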

How the results depend on the processing

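Of 81 named genes past the threshold none reversed, and 20 called lists had no reversal. Over 1667 alternative values of the 88 named genes, 1395 kept direction and side of the threshold, 239 lost the call, 22 gained it and 11 reversed; over 420 of the called lists, 362 kept both and 58 lost the call, 40 of them with an estimated correlation. The 802 called probe sets became 3359 with array weights, and, in alternatives chosen after seeing the data, 4976 without transgenic replicate 2 and with quantile normalization and 5937 without that array and with the class of Pcx ratio as a block. Leaving out 1 array gave 141 to 3565 probe sets, the highest without transgenic replicate 2. With the replicate number as a block 341 were called. This pairing has no basis in the labels. The deviations of same-numbered arrays from their group means correlated across probe sets at −0.37, 0.09 and −0.05, and 1 of 6 arrays matched its own number best. The transgenic deviations were dominated by replicate 2, whose deviations correlated at −0.88 and −0.80 with those of replicates 1 and 3. So these correlations cannot decide whether the numbers mark litters. Other settings gave 697 to 1170. The 20 called lists ranged from 18 to 22, except that an estimated correlation gave 0, with all arrays or without transgenic replicate 2. The values that changed sign belong to 3 genes near 0. For Fabp4 (0.00) leaving out 1 array gave −0.0516 to 0.0434 (below 0 without wild type replicate 2 or transgenic replicate 2 or 3), 5 arrays with the Pcx block −0.0074 (−0.0027 without the block) and the mean of all probe sets −0.81. For Fasn (−0.18) leaving out 1 array gave −0.39 to 0.18 (above 0 without transgenic replicate 2), array weights 0.18, and 5 arrays 0.11 with quantile normalization and 0.17 with the Pcx block. For Scd1 (0.01) leaving out 1 array gave −0.0293 to 0.0485 (below 0 without wild type replicate 2 or transgenic replicate 3). The cause was not tested. The arrays limit what can be seen: changes of log2 1 were not recovered in simulation with all 6 arrays (0%), and signals under about 16 carry little information. That simulation changed only 200 of 27023 probe sets, which makes the adjusted threshold harder to pass than where many change. The real fit did call some changes near log2 1, such as Plin2 (1.06) and Adipoq (−0.93). Of its 802 called probe sets, 795 had an absolute log2 fold change of at least 1.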

Other observations

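The gene lists and tests in this part were chosen after many of the values had been seen, so all of the genes named here fall outside the rule for named genes unless they stand in the report. The counts over these lists describe their members and are no test of a group, since members already seen to change prompted the lists.

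Receptors through which hormones and metabolites act on fat cells were among the genes that fell. Of 22 measured members 12 fell, 0 rose and 10 did not pass the limma test. Besides Hcar1, Hcar2 and Npr3, the melanocortin receptor gene Mc2r fell by 3.19 on the log2 scale (SE 0.37, adjusted p = 0.00775), the long-chain fatty acid receptor gene Ffar4 by 2.80 (SE 0.25, adjusted p = 0.00357) and the oxytocin receptor gene Oxtr by 2.67 (SE 0.35, adjusted p = 0.0121). The insulin receptor gene Insr had −0.35 (adjusted p = 0.533) and the adiponectin receptor gene Adipor1 0.33 (adjusted p = 0.504). Without transgenic replicate 2, 14 fell and 0 rose.

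Of 24 listed genes that PPARα is known to activate in liver 18 were measured. Of these 18, 9 rose, 1 fell and 8 did not pass the test. Genes dim in wild type fat, such as Bdh1 and Acot1, could pass the brightness filter through their transgenic signals. Such genes had little room to fall, so these counts lean towards rises. Besides Bdh1, Fabp3 and Ehhadh, the acyl-CoA thioesterase gene Acot1 rose by 2.53 ± 0.29 (adjusted p = 0.00761) and the pyruvate dehydrogenase kinase gene Pdk4 by 2.13 ± 0.33 (adjusted p = 0.0239). Vnn1 fell by 1.84 (SE 0.22, adjusted p = 0.00939), and Angptl4 had −1.20 (adjusted p = 0.0711). Without transgenic replicate 2, 11 rose and 3 fell.

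Macrophage genes did not all move the same way. Of 12 measured genes typical of lipid-associated macrophages Atp6v0d2, Mmp12, Lipa and Lgals3 (1.35, adjusted p = 0.024) rose, 0 fell and 8 did not pass the test, and without transgenic replicate 2, 10 rose. Trem2 had 1.96 (adjusted p = 0.516) and Gpnmb 3.24 (adjusted p = 0.0988), and 3.70 (adjusted p = 1.80e-05) and 4.25 (adjusted p = 4.41e-06) without that array, on which the Trem2 signal was 9.5. Of 18 genes typical of resident tissue macrophages 0 rose and 4 fell: Retnla, Mgl2, Ccl24 (−2.33, adjusted p = 0.0129) and Cd209d (−1.86, adjusted p = 0.0174). Leaving out transgenic replicate 2 gave 8 that fell and 0 that rose. The median of the lipid-associated genes exceeded that of the resident genes by at least 1.82 log2 units in each of the 3 transgenic arrays (SD 0.13 among wild type arrays). More macrophages of an unchanged kind would raise both groups, but the lists were written with these values in view and Retnla is also expressed by fat cells, so this difference decides neither for nor against that hypothesis or a change in the kind of macrophage.

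Of 24 listed genes known for high expression in liver 11 were measured. Of these 11, 5 rose, 0 fell and 6 did not pass the test, with the same counts without transgenic replicate 2. A gene dim in wild type fat could pass the brightness filter through its transgenic signals. Such a gene had little room to fall, so the counts lean towards rises. Those that rose were Aadac, Mup3 (4.11 ± 0.30 SE, adjusted p = 0.00201; its wild type signals of 2.2 to 3.7 are below the offset of 16, on which the value depends), H2-Q10 (4.16 ± 0.45 SE, adjusted p = 0.00618), Orm2 (3.61 ± 0.29 SE, adjusted p = 0.00298) and Cyp2f2. Liver RNA in the transgenic samples would bring the most abundant liver transcripts with it. Albumin reached a signal of 167.3 in transgenic and 220.2 in wild type fat, no probe set of Apoa1, Ttr or Fgb exceeded 14.2 in transgenic fat, and 0 of these 10 probe sets were brighter in every transgenic than in every wild type array, which argues against liver RNA as the source.

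The imprinted genes Nnat, Mest (−3.36, adjusted p = 0.00582), Plagl1 (−3.26, adjusted p = 0.00583) and Peg3 (−2.75, adjusted p = 0.00809) were among the large falls. Another imprinted gene, Nap1l5, rose 21.2-fold (4.40 ± 0.35 SE, adjusted p = 0.00274). The hypothesis that imprinted genes change more often than others was tested on the remaining 23 measured imprinted genes, since these 5 prompted it. Of the 23, 2 passed the threshold (8.70%), against 3.72% of 13084 other genes (Fisher's exact test, two-sided p = 0.211). Without transgenic replicate 2, 7 did so (30.4%), against 15.3% of the other genes (Fisher's exact test, two-sided p = 0.0729). The members are too few to decide it.

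Phgdh, the first enzyme of serine synthesis, fell by 4.10 on the log2 scale (SE 0.26) and the serine transporter gene Slc7a10 by 4.42 (SE 0.38). The hypothesis that serine synthesis and transport genes fall together did not hold for every member. Of 11 measured genes 2 fell, 8 did not pass the test and 1 rose. The one that rose was Psph, the last enzyme of serine synthesis, which was 4.92-fold higher (2.30 ± 0.20 SE, adjusted p = 0.00331). With transgenic replicate 2 left out 2 members rose and 3 fell.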
